A study of Homo sapiens with 6 samples.

How the data were processed

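RNA was measured on 6 Affymetrix arrays, 3 of the parental HEK293 Flp-In line and 3 of a line, set against it in the labels as its parent, that constitutively expresses TRIM71 with a FLAG-HA tag. HEK293 is an established line from human embryonic kidney. Flp-In cells carry a single recombination site into which a transgene can be placed. Total RNA was extracted with Trizol, cleaned on columns, amplified to sense-strand cDNA and labelled with biotin, per the labels' protocols. The growth protocol names hygromycin B in the medium for the TRIM71 line only. Groups and replicate numbers were taken from the sample titles.

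The deposited values were log2 expression values, 1 column per array, which the authors made with RMA, per the submitters' processing notes, which also name affy. RMA corrects the background, makes the probe distributions of the arrays equal by quantile normalization and summarises the probes of a probeset. Versions, array annotation and genome build were not given in the sources used here. Because RMA sets the probe intensities of the arrays to a common distribution, a change in the total amount of mRNA per cell cannot be seen in these values. Array medians lay between 6.90 and 6.97. The number of arrays, 3 per group, limits the precision, and log2 values of dim probesets understate fold changes.

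The table held 32321 probesets. The annotation table given for the array paired 19158 of them with 1 gene symbol, 1388 with several and 11775 with none, and no gene was named from the last 2 kinds. Of the 1-symbol probesets, 19128 matched the RefSeq gene table of GRCh38.p14 by gene ID and 30 did not, and 0 symbols had to be updated. That table was used for names, chromosomes and neighbouring genes, and no coordinates are printed because the build of the array annotation was not named. The 1-symbol probesets stood for 18404 genes, 637 of them with more than 1 probeset, and a gene was represented by its probeset with the highest mean over the arrays.

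A linear model with the group as its term was fitted to the log2 values of all 32321 probesets with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither an intensity trend nor robust estimation, and no filter on dim probesets). A probeset was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p given for a gene comes from this fit. Changes of at least 1.5-fold were also counted. TRIM71 was tested as a single value as well, with a two-sided exact permutation test, which cannot give a p below 0.1 with 3 arrays against 3. Confidence intervals are 95% intervals from the limma fit.

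The 33 gene lists, the model, the threshold, the rule for naming genes and the alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, which compares the members with all other genes, with adjustment over the 33 lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members move on balance one way and does not compare them with other genes. The genes named were TRIM71, the members of 2 lists of reported TRIM71 targets, and the 14 largest changes in each direction among called genes whose groups did not overlap and whose higher mean reached the median of all probesets. Up to 4 members of each list with the smallest adjusted p, at most 2 per direction where both directions passed, were named too. Small RNA, LOC and open reading frame symbols were left out of the largest changes.

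The procedure was tested on simulated values for the same comparison and 32321 probesets, with 200 seeded changes and the cholesterol list lowered as well. It recovered 74% of 50 probesets changed 1.5-fold, 94% of 50 changed 2-fold, 100% of 50 changed 3-fold and 100% of 50 changed 4-fold. Of 209 calls, 9 (4.31%) fell on unchanged probesets, and the rest on seeded probesets or the lowered list. The simulated noise was drawn for each probeset on its own, and few probesets were changed. These shares therefore need not hold for the real arrays, where many more probesets were called and noise may be shared. The alternatives were an intensity trend with and without robust estimation, 3 further normalizations, 2 filters on dim probesets, 1 probeset per gene before the adjustment, the replicate number as a block, array weights, a test against a fold of 1.2, an adjusted p under 0.01, other set tests, another collapse of probesets, and each array left out in turn. Counts and lists without the genes of chromosome 2 were added after the data had been seen.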

Results

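Genome-wide mRNA levels were measured in 2 groups of 3 arrays, the parental HEK293 Flp-In line and a line that constitutively expresses tagged TRIM71. TRIM71 is an RNA-binding protein of the TRIM-NHL family, known from stem and progenitor cells. The comparison asks which mRNAs differ in level between the TRIM71 line and its parent, a line of embryonic kidney origin. Hygromycin B is named for the medium of the TRIM71 line only. For every gene, the transgene, the drug and other differences between the lines are therefore not separated. Pearson correlations over all probesets were 0.996 to 0.997 within groups and 0.991 to 0.994 between groups. The labels say only that the experiment was done in triplicate, so the p-values measure the spread between these samples, which may be technical. Values are log2 expression as mean ± SD with n = 3 per group, and fold changes are the TRIM71 line over the parental line.

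TRIM71 mRNA was 10.1-fold higher in the line that expresses it, at 10.74 ± 0.11 against 7.40 ± 0.16 in the parental line (log2 fold change 3.33, SE 0.10, adjusted p = 6.8e-05). The lowest TRIM71 array stood at 10.64 and the highest parental array at 7.54, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. Of 4 mRNAs reported as TRIM71 targets by work that may have used these arrays, 3 fell. PLXNB2, a semaphorin receptor, went from 9.42 ± 0.03 to 8.53 ± 0.01 (log2 fold change −0.89, adjusted p = 2.1e-04), and E2F7, a repressive cell cycle transcription factor, from 10.21 ± 0.05 to 9.52 ± 0.06 (−0.69, adjusted p = 7.9e-04). RBL1, a pocket protein, fell by less (−0.23, adjusted p = 0.017), and its relative RBL2 differed by −0.13 without passing the test (adjusted p = 0.146).

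Adjusted over the list alone, all 4 of these genes were lower. That count is not independent evidence if the list was chosen on these arrays. The RBL1 call ended without parental replicate 2 (log2 fold change −0.23, adjusted p = 0.068), parental replicate 3 (−0.24, 0.055), TRIM71 replicate 1 (−0.23, 0.061) or TRIM71 replicate 2 (−0.22, 0.062). Of 5 mRNAs reported as targets in other systems, 3 fell, both genome-wide and adjusted over the list alone. These were the splicing regulators MBNL2 (−0.60, adjusted p = 9.5e-04) and MBNL1 (−0.36, adjusted p = 0.0043) and the CDK inhibitor CDKN1A (−0.54, adjusted p = 0.0074). EGR1 (−0.02, adjusted p = 0.87) and AGO2 (0.02, adjusted p = 0.89) did not pass, and the direction of AGO2 changed with quantile normalization. The first list was lower than other genes (median −0.46, adjusted p = 0.0040; adjusted p = 0.31 with an estimated correlation), as was the second (median −0.36, adjusted p = 0.044; adjusted p = 0.36 with an estimated correlation). The second call ended without parental replicate 1 (adjusted p = 0.051), parental replicate 3 (0.070) or TRIM71 replicate 1 (0.053), with either filter on dim probesets, with the replicate block, and without chromosome 2, while its mean shift against other genes stayed between −0.28 and −0.26.

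**Figure D1:**
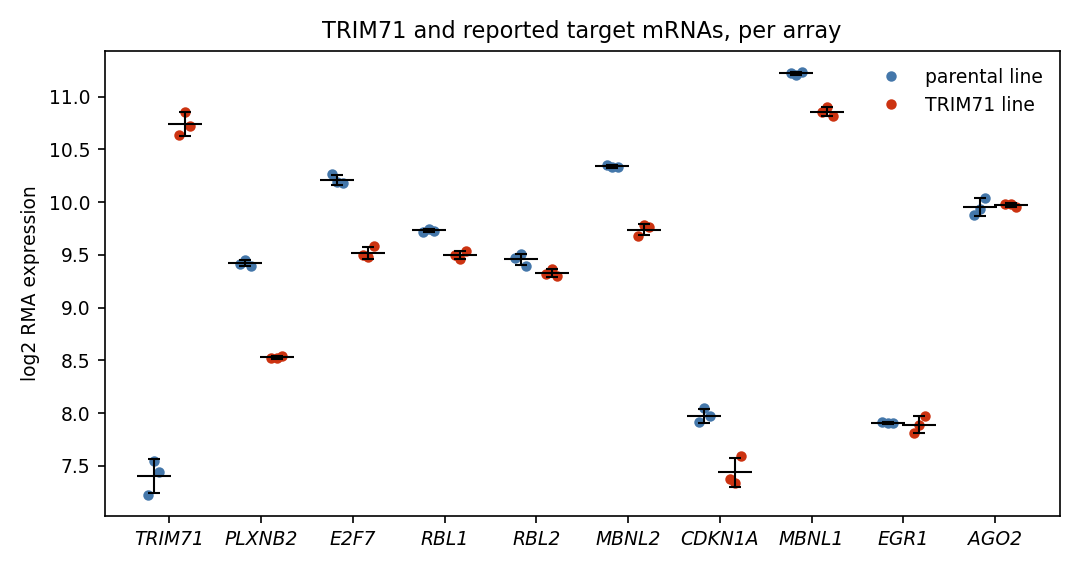
Log2 expression of TRIM71 and of 9 reported target mRNAs, with a point per array, the mean as a bar and the SD as whiskers (n = 3 per group). TRIM71 lies at 10.74 in its line against 7.40 in the parental line, PLXNB2 at 8.53 against 9.42, and the AGO2 groups overlap.

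In total, 1848 genes rose and 2244 fell in the TRIM71 line, or 22.2% of 18404 genes tested. By at least 1.5-fold, 232 rose and 498 fell. By at least 2-fold, 47 rose and 154 fell. For every gene described here as risen or fallen by the rule for naming genes, all 3 TRIM71 arrays lay on the same side of all 3 parental arrays. The groups did not overlap for 8019 genes (43.6%), where chance gives 10%. Leaving out 1 array moved the number that rose by over 1.5 times for parental replicate 2 (994 genes), parental replicate 3 (1185), TRIM71 replicate 1 (1121) and TRIM71 replicate 2 (979). The number that fell moved as far for parental replicate 2 (1365 genes) and TRIM71 replicate 1 (1336).

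Under the rule for naming genes, the largest rises after TRIM71 itself were of IFI16, a DNA sensor (6.08 ± 0.03 to 8.86 ± 0.09, log2 fold change 2.78, adjusted p = 2.4e-05), and APOBEC3B, a cytidine deaminase (7.16 ± 0.37 to 9.90 ± 0.09, 2.75, adjusted p = 5.1e-04). CALCB, a calcitonin gene-related peptide, rose by 2.47, F2RL2, a thrombin receptor family member, by 2.12, and HAS2, a hyaluronan synthase, by 2.03. HSPB8 (1.81), PRTG (1.68), ADAMTS9 (1.60), RAB3C (1.57), SULT1C4 (1.55), PKDCC (1.53), FLI1 (1.47) and ANXA1 (1.40) made up the rest of the 14 largest rises, with adjusted p between 6.8e-05 and 5.7e-04. The largest fall under the same rule was of the probeset named H3C11, a replication-dependent H3 histone, from 11.70 ± 0.05 to 7.38 ± 0.04 (log2 fold change −4.32, 19.9-fold lower, adjusted p = 1.3e-06). Histone genes of this kind have near-identical copies, so the identity of this mRNA is uncertain. A probeset shared by H3C11 and H3C6 did not pass (0.03, adjusted p = 0.89), but at 5.90 in the parental line it was too dim to say much. ALDH1L2, a mitochondrial folate enzyme, fell from 9.91 ± 0.24 to 6.42 ± 0.34 (−3.49, adjusted p = 2.8e-04) and SCIN, an actin-severing protein, from 8.97 ± 0.06 to 6.01 ± 0.06 (−2.96, adjusted p = 1.3e-05). A probeset annotated to a single RAC1 transcript fell by 2.54 on the log2 scale and need not stand for the gene as a whole. SPAG6 (−2.32), the inositol trisphosphate receptor ITPR3 (−2.27), QRFPR (−2.23), ZNF528 (−2.17), PRTFDC1 (−2.14), the cadherin CDH3 (−2.10), RNF122 (−2.09), CHAC1 (−2.02), GPR50 (−1.92) and PXDN (−1.92) followed. The other QRFPR probeset was dim and did not pass (−0.31, adjusted p = 0.11).

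Among the 33 lists, the largest share of fallen members was in ATF4 and amino acid stress response genes, which encode the transcription factor ATF4 and its targets in amino acid import and synthesis. Of 30 measured members, 28 fell, 0 rose and 2 did not pass, and 29 were lower adjusted over the list alone. By at least 1.5-fold 20 fell, and by at least 2-fold 11. The median log2 fold change was −0.70. CHAC1, a glutathione-degrading enzyme, fell by 2.02 on the log2 scale, SLC7A11, the cystine transporter subunit, from 11.22 ± 0.11 to 9.33 ± 0.01 (−1.89, adjusted p = 9.5e-05), CTH, a cysteine-forming enzyme, by 1.60 and SLC7A5, a transporter of large neutral amino acids, by 1.06. ATF4 mRNA itself fell (−0.64, adjusted p = 0.0013). The members that did not pass were PPP1R15A (−0.16, adjusted p = 0.162) and ATF5 (−0.08, adjusted p = 0.496). The list was lower than other genes (adjusted p = 6.6e-20; adjusted p = 0.29 with an estimated correlation). Hygromycin B in the medium went with the TRIM71 line, so drug and transgene are not separated in any array.

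**Figure D2:**
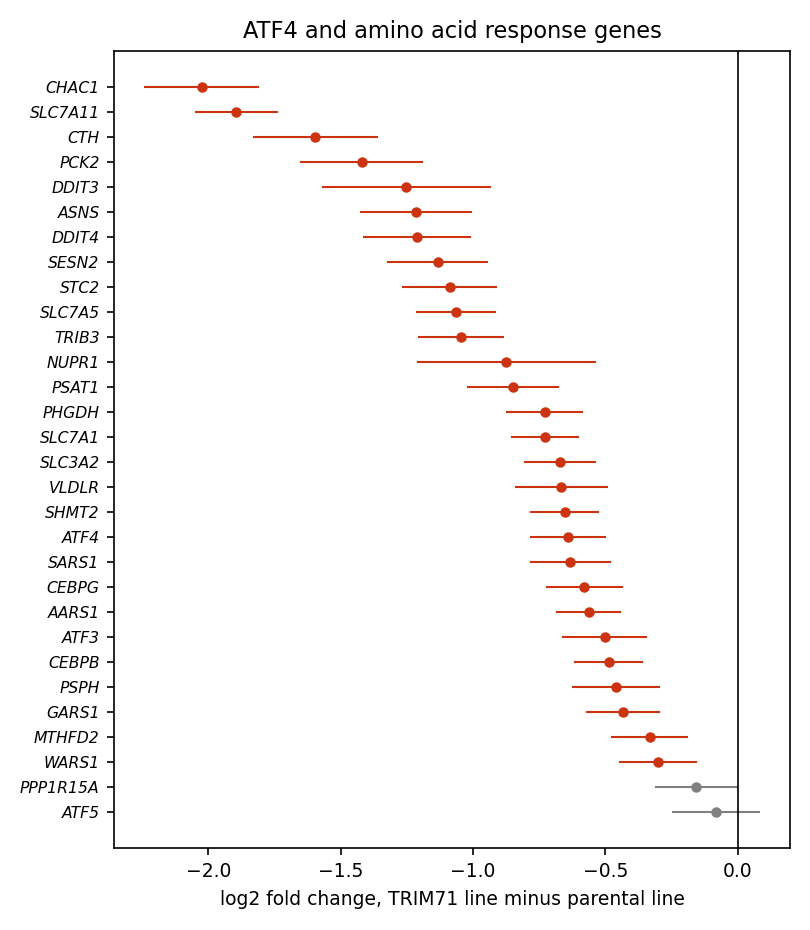
Log2 fold change of the TRIM71 line over the parental line for the 30 measured ATF4 and amino acid stress response genes, with 95% confidence intervals from limma (n = 3 arrays per group). Red marks the 28 members past an adjusted p of 0.05, from CHAC1 at −2.02 upwards, and grey the 2 that did not pass.

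Of 56 replication-dependent histone genes, 23 fell, 0 rose and 33 did not pass (34 lower adjusted over the list alone; median −0.25), among them H2AC8 (−1.16), H2AC16 (−1.05) and H3C10 (−0.74). The list was lower than other genes (adjusted p = 6.4e-09; adjusted p = 0.29 with an estimated correlation), and the near-identical copies make single members uncertain. Of 57 ribosomal protein genes, 11 fell, 0 rose and 46 did not pass, with the same numbers adjusted over the list alone (median −0.09, adjusted p = 3.6e-04; adjusted p = 0.52 with an estimated correlation). RPL13 fell by 0.68 on the log2 scale at its brightest probeset, as it did at a second (−0.37, adjusted p = 0.012), and another of its probesets did not pass (−0.11, adjusted p = 0.52). RPL27A (−0.38), RPS24 (−0.29) and RPL12 (−0.27) fell as well. The other 2 probesets of RPL27A did not pass (−0.52, adjusted p = 0.085, and −0.13, adjusted p = 0.50), and of the other 3 of RPL12, 2 fell (−0.32 and −0.29) and 1 did not pass (−0.19, adjusted p = 0.37).

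Members of the cell cycle lists changed in both directions. Of 39 DNA replication and G1/S genes, 12 fell, 3 rose and 24 did not pass (18 and 6 adjusted over the list alone; median −0.14). CCNE2, a cyclin of the G1/S transition, fell from 9.67 ± 0.11 to 8.17 ± 0.07 (−1.50, adjusted p = 2.1e-04) and the licensing factor CDT1 by 0.57, while the related cyclin CCNE1 rose by 0.40. Of 41 G2/M and mitosis genes, 11 rose, 4 fell and 26 did not pass (13 and 4 adjusted over the list alone; median 0.12), with UBE2C (0.49) and the checkpoint kinase BUB1B (0.42) higher and the phosphatase CDC25B (−0.73) and separase ESPL1 (−0.46) lower. The first list was lower than other genes (adjusted p = 0.016; adjusted p = 0.54 with an estimated correlation) and lost its call without parental replicate 1 (adjusted p = 0.079) or TRIM71 replicate 3 (0.070). The second was higher (adjusted p = 0.0052; adjusted p = 0.54 with an estimated correlation).

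CDK inhibitors and pocket proteins were lower, with 4 of 9 fallen and 0 risen, the same numbers adjusted over the list alone (median −0.14, adjusted p = 0.013; adjusted p = 0.29 with an estimated correlation). CDKN1A and RBL1 are given above, CDKN1B fell by 0.31, and RB1 fell by 0.29 with a call that any 1 array left out ended (adjusted p between 0.058 and 0.103). Of 10 E2F factors, 2 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.86), with E2F5 higher (0.74) and E2F7 lower. Of 26 p53 target genes, 11 fell and 4 rose (12 and 7 adjusted over the list alone; adjusted p = 0.15). SESN2, which the ATF4 list also holds, fell by 1.13 and SPATA18 by 1.02, while TIGAR rose by 0.54 and TNFRSF10B by 0.44.

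Of 27 let-7 target genes, which that microRNA is known to repress, 13 rose and 4 fell (14 and 6 adjusted over the list alone; median 0.21, adjusted p = 0.0032; adjusted p = 0.29 with an estimated correlation). PRTG, a cell surface protein of the immunoglobulin superfamily, rose from 8.94 ± 0.08 to 10.62 ± 0.07 and the nuclear receptor NR6A1 by 1.37, while PLAGL1 (−1.70) and MYC (−0.58) fell. Of 20 microRNA machinery genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.0045; adjusted p = 0.29 with an estimated correlation). AGO1 rose by 0.61 and DICER1, which both lists hold, by 0.29, and the helicase MOV10 fell by 0.29.

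Of 36 mRNA deadenylation and decay factors, 9 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.10), with the antiproliferative factor TOB1 (0.40) and CNOT9 (0.29) higher. The list was higher than other genes (adjusted p = 0.014; adjusted p = 0.52 with an estimated correlation), but not without the genes of chromosome 2 (adjusted p = 0.059), where CNOT9 lies, and the mean shift against other genes moved from 0.10 to 0.089. Of 18 heat shock genes, 7 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.19, adjusted p = 0.0053; adjusted p = 0.52 with an estimated correlation). DNAJB1, a co-chaperone, rose by 0.83 and the mitochondrial co-chaperonin HSPE1, which lies on chromosome 2, by 0.53, while HSPB1 fell by 0.36. Of 11 nonsense-mediated decay factors, 1 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.29), with SMG8 higher (0.44) and SMG9 lower (−0.26). Of 20 endoplasmic reticulum chaperone and unfolded protein response genes, 6 rose and 5 fell (6 and 6 adjusted over the list alone; adjusted p = 0.51). HSPA5 rose by 0.33 and HYOU1 by 0.28, while HERPUD1 (−0.67) and EDEM1 (−0.61) fell.

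**Figure D3:**
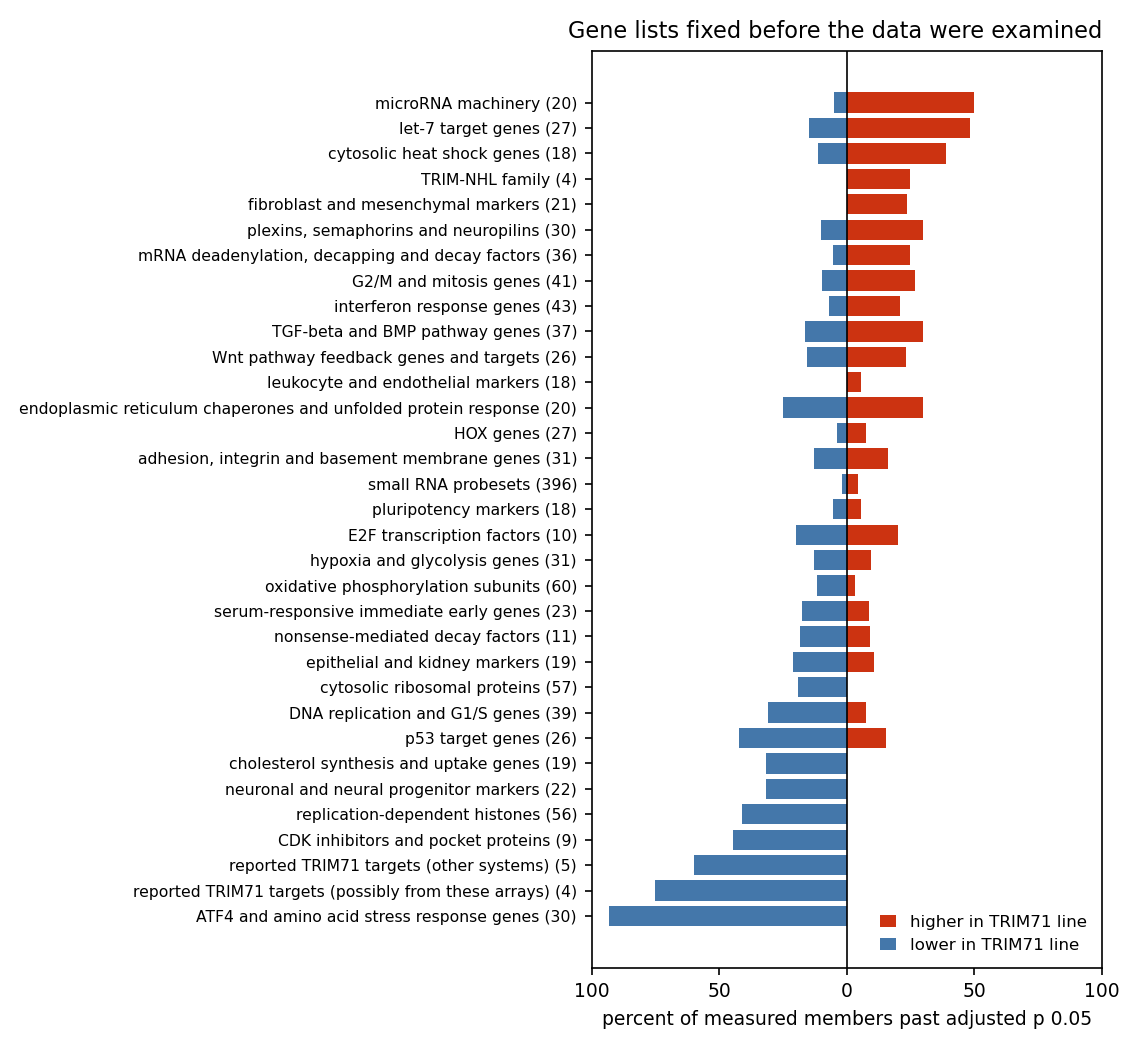
Percent of the measured members of each of 33 gene lists that were higher (red, right) or lower (blue, left) in the TRIM71 line at a limma adjusted p under 0.05, with the number of measured members in brackets. In the ATF4 list 28 of 30 members were lower, and in the microRNA machinery list 10 of 20 were higher.

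Of 22 neuronal and neural progenitor markers, 7 fell, 0 rose and 15 did not pass (8 and 0 adjusted over the list alone; median −0.15), including the neurofilament NEFL (12.41 ± 0.04 to 10.96 ± 0.05, −1.45, adjusted p = 9.5e-05), MAP2 (−1.21), RBFOX3 (−1.07) and INA (−0.62). The other RBFOX3 probesets, dim at 6.30 and 3.61 in the parental line, did not pass (−0.03 and −0.01). The list was lower than other genes (adjusted p = 0.025; adjusted p = 0.54 with an estimated correlation), but not without the genes of chromosome 2 (adjusted p = 0.093), where MAP2 lies, and the mean shift against other genes moved from −0.25 to −0.19. Over the 18 alternatives run for this list the value ranged from −0.45 to −0.19. Of 19 epithelial and kidney markers, 4 fell and 2 rose (4 and 3 adjusted over the list alone; adjusted p = 0.58). E-cadherin, CDH1, fell by 1.66 and EPCAM by 1.47, with both EPCAM probesets alike, while the endocytic receptor LRP2 rose by 1.40.

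Of 21 fibroblast and mesenchymal markers, 5 rose and 0 fell (5 and 1 adjusted over the list alone; adjusted p = 0.065). These included ZEB1, a repressor of CDH1 (0.76), fibronectin FN1 (0.70), N-cadherin CDH2 (0.42) and vimentin VIM (0.40). The parental line already had VIM at 11.11 and FN1 at 10.34. The list passed without parental replicate 2 (adjusted p = 0.038), without TRIM71 replicate 2 (0.043) and with either filter on dim probesets. Of 18 leukocyte and endothelial markers, 1 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.51). KDR, an endothelial growth factor receptor, rose from 4.99 ± 0.14 to 6.42 ± 0.33, below the median of all probesets at 6.94. Of 18 pluripotency markers, 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.71), namely DNMT3B (0.41) and SOX2 (−0.46). Of 27 HOX genes, 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.51), with HOXA2 higher (8.48 ± 0.02 to 9.48 ± 0.06) and HOXD13 lower (−0.58).

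Signalling lists held changes in both directions. Of 37 TGF-beta and BMP pathway genes, 11 rose and 6 fell (11 and 8 adjusted over the list alone; adjusted p = 0.30), with BMP2 (1.01) and ACVR2B (0.60) higher and TGFB2 (−0.95) and ID4 (−0.81) lower. Of 26 Wnt pathway genes, 6 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.057), with the receptor FZD7 (1.11) and the feedback gene AXIN2 (0.74) higher and the secreted inhibitor SFRP2 (−1.30) lower. This list passed with quantile normalization (adjusted p = 0.041) and without TRIM71 replicate 1 (0.046). Of 30 plexins, semaphorins and neuropilins, 9 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.28), with PLXNA2 (0.64) and SEMA3C (0.55) higher and PLXNB2 lower. Of 23 immediate early genes, 2 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.84), with the phosphatases DUSP5 (1.35) and DUSP1 (0.34) higher and MYC and ATF3 (−0.50) lower. Of 43 interferon response genes, 9 rose and 3 fell (11 and 4 adjusted over the list alone; adjusted p = 0.29), with SAMD9 (0.94) and IFITM3 (0.78) higher and IFI44L (−0.80) and OAS3 (−0.66) lower.

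Of 19 cholesterol genes, 6 fell and 0 rose (9 and 2 adjusted over the list alone; adjusted p = 0.089), among them SQLE (−0.37), DHCR7 (−0.31), INSIG1 (−0.31) and EBP (−0.30), and the list passed without parental replicate 2 (adjusted p = 0.044) or TRIM71 replicate 2 (0.041). Of 31 hypoxia and glycolysis genes, 3 rose and 4 fell (3 and 5 adjusted over the list alone; adjusted p = 0.67), with the glucose transporter SLC2A3 (1.10) and KDM3A (0.50) higher and VEGFA (−0.86) and NDRG1 (−0.74) lower, and the mean shift of the list changed sign with quantile normalization. Of 60 oxidative phosphorylation subunits, 2 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.11), with UQCRQ (−0.61) and NDUFV1 (−0.45) lower, and the list passed without TRIM71 replicate 2 (adjusted p = 0.042) and with an intensity trend (0.048). Of 31 adhesion and basement membrane genes, 5 rose and 4 fell (7 and 6 adjusted over the list alone; adjusted p = 0.79), with the integrins ITGAV higher (0.67) and ITGA2 lower (−0.63). Of 4 TRIM-NHL genes only TRIM71 rose, also adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.12), but passed without parental replicate 1 (0.047) and with fry (0.0012). Its median was 0.045, so its mean and these passes rest on TRIM71 itself and say nothing about the other members. Of 396 small RNA probesets, 17 rose and 8 fell (9 and 2 adjusted over the list alone; adjusted p = 0.15), with SNORD12C higher by 0.71.

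Further members that the rule for naming genes took are given here, 12 of them with calls that leaving out 1 array ended. Among these, CLSPN (0.41, adjusted p = 0.014, up to 0.056 without 1 array), the homeobox gene HOXC13 (0.43, adjusted p = 0.028, up to 0.093), LHX1 (0.30, adjusted p = 0.028, up to 0.081), NDUFB4 (0.22, adjusted p = 0.020, up to 0.081) and NDUFB2 (0.21, adjusted p = 0.034, up to 0.106) were higher. TFDP1 (−0.26, adjusted p = 0.019, up to 0.067), the decay factors BTG1 (−0.29, adjusted p = 0.020, up to 0.076) and CNOT10 (−0.32, adjusted p = 0.021, up to 0.072), SMG5 (−0.24, adjusted p = 0.023, up to 0.068), SEMA4G (−0.31, adjusted p = 0.031, up to 0.10), HSPA4L (−0.22, adjusted p = 0.027, up to 0.091) and MIR196A1 (−0.36, adjusted p = 0.013, up to 0.054) were lower. The replicate block ended the calls of all 12 but CLSPN, and those of RBL1, RB1, SMG9, DHCR7 and RPL12, and median centring ended those of RB1, HSPA4L, NDUFB4 and NDUFB2. The calls of E2F6 (0.35), the laminin LAMC1 (0.34), SNORD50A (0.47), the syndecan SDC3 (−0.46) and SNORD13P1 (−0.44) held without any 1 array. SNORD13P1 was dim, at 3.33 in the parental line and 2.89 in the TRIM71 line, so its change says little. TRIM2 (0.09, adjusted p = 0.39), TRIM3 (−0.01, adjusted p = 0.95), TRIM32 (0.0008, adjusted p = 0.996), LYZ (0.18, adjusted p = 0.20), CD52 (0.15, adjusted p = 0.36) and HBB (−0.17, adjusted p = 0.43) did not pass.

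Of the 33 lists, 5 were called higher and 8 lower, and 0 were called with an estimated correlation. That setting ended calls even where the estimate lay near or below the preset 0.01. These were the CDK inhibitors (−0.0034), the microRNA machinery (−0.018) and the second reported targets (0.011). For these lists a higher correlation between members does not account for the lost call, and what does was not tested. Fry, which asks only whether members moved on balance one way, called 23. The median, mean and test differed in sign for 6 lists, none of them called, namely the E2F factors, leukocyte and endothelial markers, plexins, endoplasmic reticulum chaperones, immediate early genes and adhesion genes.

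Changes were spread unevenly over the chromosomes, which was examined after the data had been seen. On chromosome 2, 323 genes rose and 74 fell of 1154 tested, so that 81.4% of the changed genes were higher, against 45.2% over all genes (Fisher's exact test, adjusted p = 2.7e-53 over the chromosomes, with genes counted as if independent). SULT1C4, PKDCC, LRP2, FN1, FZD7 and ITGAV lie there, and PXDN and EPCAM, which fell, do too. Chromosome 15 (112 higher, 57 lower), chromosome 7 (122 higher, 66 lower) and chromosome 3 (145 higher, 106 lower) leaned the same way. Chromosome 14 (35 higher, 103 lower), chromosome 11 (60 higher, 164 lower) and chromosome 19 (70 higher, 176 lower) leaned the other way. At an adjusted p under 0.05 the same test also called chromosome 20 towards higher genes. Towards lower genes it called chromosomes 4, 6, 9, 10, 12, 17 and 21, so the unevenness was widespread. Without chromosome 2, 1525 genes rose and 2170 fell.

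**Figure D4:**
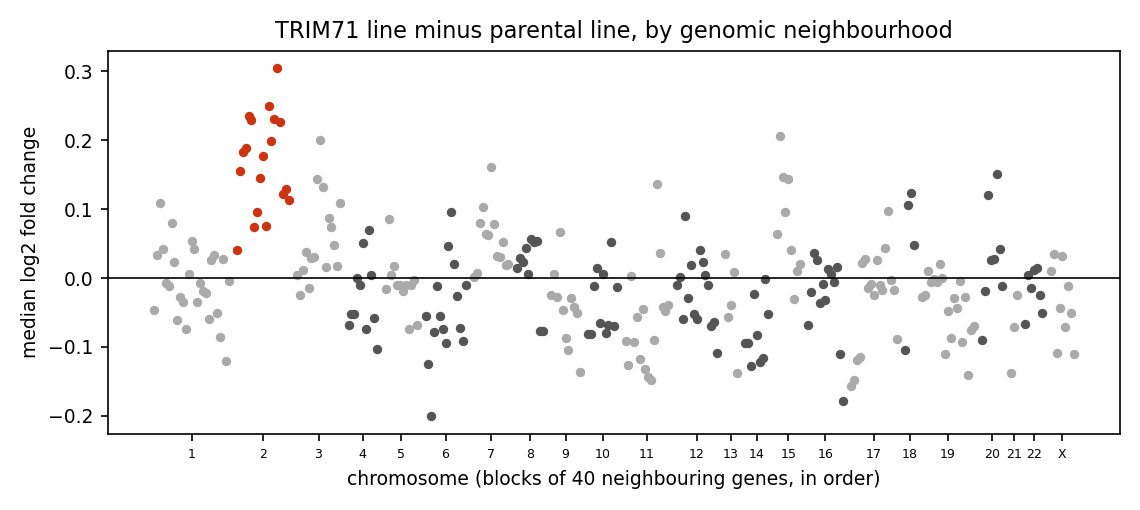
Median log2 fold change of the TRIM71 line over the parental line in blocks of about 40 neighbouring genes, a point per block, in order along each chromosome. Only genes with a mean at or above the median of all probesets were placed in blocks (740 of 1154 on chromosome 2, with a median of 0.17 against 0.08 over all its genes). The 19 blocks of chromosome 2 (red) lie between 0.04 and 0.30.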

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

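Signal outside the gene-level comparison was found in the probesets to which no single gene could be assigned. Of 11775 probesets with no gene symbol, 578 were higher in the TRIM71 line than in the parental line at a limma adjusted p under 0.05 and 254 were lower, and by at least 1.5-fold 186 were higher and 42 lower. Of 1388 probesets with several gene symbols, 90 were higher and 114 lower. No explanation was tested for either group. Outlying samples were not looked for, because each group held 3 arrays, and the design has a single contrast, so no effects of different groups could be set against each other.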

How the results depend on the processing

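The alternatives without the genes of chromosome 2 were chosen after seeing the data, and the others before. TRIM71 stayed past the threshold in each of 17 alternatives, with a log2 fold change of 3.25 to 3.404, and the median over all genes moved by less than 0.1 in each. The cause of the changes below was not tested, except that leaving out an array leaves fewer samples and a stricter threshold makes fewer calls. Against 1848 genes higher and 2244 lower, the test against a fold of 1.2 gave 232 and 471 (33.0% of calls higher), and an adjusted p under 0.01 gave 792 and 1106. Counts without 1 array ranged from 979 to 1485 higher and 1336 to 1709 lower. With the replicate block, 1019 genes were higher and 1371 lower, and 2362 of the 4092 calls were shared. The labels do not say whether the replicate numbers pair the samples. Deviations from the group means correlated at 0.068, −0.188 and 0.108 for numbers 1, 2 and 3, and not every sample correlated best with its own number. With 3 arrays per group these values cannot settle whether the samples were paired.

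List values are mean log2 fold changes of members minus other genes. With an estimated correlation, 13 calls were lost at ATF4 −0.82, first reported targets −0.46, histones −0.35, second reported targets −0.28, neuronal −0.25, CDK inhibitors −0.19, G1/S −0.11, ribosomal proteins −0.091, heat shock 0.22, let-7 targets 0.21, microRNA machinery 0.17, G2/M 0.11 and mRNA decay 0.10. The second reported targets lost their call with the median filter (−0.28), the 25th percentile filter (−0.27), the replicate block (−0.28) and without chromosome 2 (−0.27), where mRNA decay (0.089) and neuronal markers (−0.19) lost theirs. Lists gained a call as follows: oxidative phosphorylation with an intensity trend (−0.040), Wnt with quantile normalization (0.10), and fibroblast markers with the median (0.29) and 25th percentile (0.19) filters. Fry, whose values are means of members, called TRIM-NHL (0.85), p53 (−0.14), nonsense-mediated decay (0.057), epithelial (−0.12), fibroblast (0.11), interferon (0.063), cholesterol (−0.11), TGF-beta (0.033), Wnt (0.073) and oxidative phosphorylation (−0.064). The TRIM-NHL values here and below rest on TRIM71 itself.

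Without 1 array, values of lists whose call changed ranged from −0.29 to −0.26 for the second reported targets, 0.85 to 0.90 for TRIM-NHL, −0.13 to −0.083 for G1/S, 0.12 to 0.15 for fibroblast, −0.11 to −0.070 for cholesterol, 0.087 to 0.11 for Wnt and −0.059 to −0.018 for oxidative phosphorylation. The sign differed in 24 cases, past no threshold in either setting. These were AGO2 with quantile normalization (−0.0053), TRIM32 with quantile normalization (−0.0017), median centring (−0.0038) and cyclic loess (−0.010), TRIM3 with cyclic loess (0.000695), hypoxia genes with quantile normalization (0.0025) and the 25th percentile filter (0.00057), endoplasmic reticulum chaperones with fry (−0.014), and adhesion genes with fry (−0.0094) and without chromosome 2 (−0.022). The values with fry are means of members, which are the same in the main fit. Their sign differs only because the main values subtract the other genes. Without 1 array, values ranged from −0.020 to 0.061 for AGO2, −0.060 to 0.021 for EGR1, −0.025 to 0.024 for TRIM3, −0.038 to 0.058 for TRIM32, −0.023 to 0.035 for hypoxia genes and −0.0024 to 0.034 for chaperones.

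Named genes lost their call in 54 cases in the test against a fold of 1.2, 16 with the block, 4 with median centring and 6 to 13 without 1 array. Camera has no robust option, so the robust trend was not run for lists, and dim genes have no value under the filters. Probesets near the background limit how small a fold can be seen.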

Other observations

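The zinc finger genes, the gene groups of the next paragraph and the tests of brightness, hygromycin and chromosomes were chosen after the result was seen. Fisher's exact tests below count genes as if independent. Members were counted in 5 further groups, 4 of them given in the next paragraph. The last holds genes named as zinc fingers by symbol, such as ZNF, ZFP, ZSCAN and ZKSCAN, called zinc finger genes here. Zinc finger genes with other names are not in it. Of its 524 genes, 120 fell and 47 rose (Fisher's exact test for falls, adjusted p = 1.9e-11 over 5 groups).

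Of 15 cytosolic aminoacyl-tRNA synthetases outside the fixed list, which charge tRNAs with amino acids, 8 fell and 0 rose in the TRIM71 line (median −0.25), more falls than among all other genes (Fisher's exact test, adjusted p = 3.5e-04 over 5 groups). CARS1 (−0.87), YARS1 (−0.68) and MARS1 (−0.42) were among them. Of 16 mitochondrial synthetases, 3 fell and 2 rose (adjusted p = 0.54). Of 24 amino acid transporters outside the list, 7 fell and 7 rose (adjusted p = 0.035 for falls and 0.038 for rises), so they changed more often than other genes in both directions, with SLC6A9 (−1.87), SLC1A4 (−1.60) and SLC7A3 (−1.50) lower and SLC1A3 (0.58) and SLC38A7 (0.49) higher. Of 20 genes of the cadherin family, CDH1 and CDH3 fell and CDH2 rose (adjusted p = 1 for falls).

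Of the 30 ATF4 response genes, 28 were lower in the TRIM71 line. The list was lower than other genes with camera's preset correlation, and that call was lost with an estimated correlation (adjusted p = 0.29). The number of members lower was at least 26 of 30 whichever array was left out, so a single array is not the whole cause. Of 10000 random lists matched on mean expression, 0 had a median as low as −0.70 (lowest −0.16), which argues against mean brightness as the whole cause. The list was singled out for its falls, and the draws used the same normalized values, so they do not test normalization between arrays. Hygromycin in the medium cannot be told apart from the transgene, because 0 arrays separate them. A lower amino acid stress response in the TRIM71 line may come from either, or from any other difference between the lines or their culture, and this stays a hypothesis.

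Genes of chromosome 2 were shifted upwards (median 0.08 over 1154 genes). Of all its genes, changed or not, 68.5% lay above the median of other chromosomes (95% interval 65.4% to 71.7% from 29 resampled blocks of neighbours), so a few strongly changed genes are not the whole cause. Of 10000 sets matched on mean expression, 0 had a median as high (highest 0.0056), which argues against mean brightness as the whole cause. The draws used the same normalized values, so they do not test normalization. Among its 740 genes with a mean at or above the median of all probesets, 19 of 19 blocks of about 40 neighbouring genes had a positive median. With all 1154 genes, 28 of 29 blocks did. More copies of the chromosome in the TRIM71 line could give this, as a hypothesis. The chromosome was picked for its upward shift, so positive blocks partly restate that shift. DNA was not analysed here, chromosome 7 had 13 of 13 positive blocks among the brighter genes but 14 of 21 with all genes, chromosome 14 had 0 of 9 and 0 of 15, and a wider difference between sublines of HEK293 stays open.

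Zinc finger genes on chromosome 19 fell more often than others, with 79 of 244 lower (32.4%). Elsewhere, 41 of 280 zinc finger genes were lower (14.6%, Fisher's exact p = 2.2e-06 against those of chromosome 19). Of the other genes of the chromosome, 97 of 1064 were lower (9.12%, Fisher's exact p = 2.3e-18 likewise). Both tests count genes as if independent, and the set was chosen after its falls were seen. The other genes may hold zinc finger genes with other names. Of 10000 sets matched on mean expression, 0 held as many lower calls (highest 54), which argues against mean brightness as the whole cause. The set was singled out for its falls, and the draws used the same normalized values, so they do not test normalization. Loss of a segment cannot be told apart from regulation of single genes. The 30 brighter genes that fell by at least 1.5-fold had a median of −0.96. Neighbours were taken among the brighter genes of the chromosome. Dim genes in between were passed over, so a neighbour here need not be the adjacent gene. Of the 53 neighbours of the fallen genes, 21 were fallen genes of the same set. The other 32 had a median of −0.14, but leaving out the fallen ones makes that value small by choice. Counted once per side and with the fallen ones kept, 60 neighbours had a median of −0.47 (bootstrap 95% interval −0.69 to −0.20), 35 of them lower, which holds the pattern's own genes. Neighbours chosen by class, those without a zinc finger symbol, had a median of −0.12, with 2 of 5 lower. They were too few to decide (bootstrap 95% interval −1.72 to 0.12). Zinc finger genes have close copies, so probesets may share signal.

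The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave as many calls as it did: 1848 genes higher against at most 0 in other splits, 2244 lower against 0, 232 higher by 1.5-fold against 0, and 498 lower by 1.5-fold against 0. The real split called 13 lists and the others 3 to 8, so camera with its preset correlation calls lists in splits that call 0 genes. Those splits still hold part of the difference between the lines, so these are not calls on null data. Mixing the lines also widens the spread within each group of a split, so the 0 gene calls there say little about chance.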
